A study of Mus musculus with 21 samples.

How the data were processed

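RNA was measured in 18 libraries of sorted β-cells, 5 WT, 8 Ldb1-KO and 5 Isl1-KO, and protein binding to DNA in whole islets with 1 LDB1 and 1 ISL1 ChIP-seq sample. Per the labels' protocols, islets were dispersed with trypsin, lineage-marked cells were sorted into TRIzol, total RNA was purified and libraries were made with a ScriptSeq low-input kit. The mice for RNA had a mixed SV/129 and C57Bl/6 background, and each round of tamoxifen was 5 gavages. The LDB1 sample was precipitated with an antibody that its label names CLIM-2. An input sample of the same islets was not analysed here. Groups and replicate numbers were taken from the sample titles, and each column of the expression table was matched to a sample by its name, with 0 columns of per-sample values left unused.

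The authors' deposited table gives 1 row per gene symbol, 21913 in all, with 1 value per library on a log2 scale. The labels do not state its normalization. From the values it was read as log2 of quantile-normalized values plus 1. The lowest value is 0, and all 18 libraries share the highest value, 18.29, with further top values on a common ladder. Values at equal ranks were not always the same, with 17.01 at rank 2 in WT replicate 1 and 17.975 in WT replicate 2. The reading therefore stays an inference. The deposited log2 fold changes, p-values and FDRs of the 3 comparisons stand in the same table, whose sheet is named after edgeR, a tool also named in the submitters' processing notes. The ratio of deposited FDR to p-value shows that the authors adjusted over 28644 tests, more than the table's rows. Aligner and counting steps are not given in the sources used here, beyond HOMER, edgeR and the mouse build mm9 in the submitters' processing notes. The deposited peak lists give a position and a score per peak. The unit of the score is not given in the sources used here, and the peak caller is given only as far as HOMER stands in the submitters' processing notes.

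The test planned first needed raw counts. The table holds log2 values, so the test planned for normalized values was used. Genes with a mean normalized value of at least 1 over the 18 libraries were kept, which left 13501. Differences were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3 (moderated statistics with an intensity trend and robust settings, statmod 1.5.0) in 1 fit of all 18 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are therefore of values plus 1 and are smaller than the true changes of genes near 0. SE is the moderated standard error of the log2 difference. The labels give shared replicate numbers across groups, and the fit did not use them.

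Quantile normalization leaves no library totals, so absolute depth is unknown and no interval from counts is given. The normalized value per read step was taken as the value at the 20th distinct step of a library divided by 20, and a smaller value means a deeper library. Libraries whose 20th step lay below 20 were called deeper, 2 in WT (replicates 1 and 5), 5 in Ldb1-KO and 1 in Isl1-KO. Values of the most abundant genes sit on a coarse ladder, with gaps of up to 1.02 between neighbouring top values. The scripts were tested on simulated data with normal noise in which 200 of 13501 genes were changed. The changed genes were drawn only from those above a minimum WT mean, so the shares below do not cover the most weakly expressed genes. In the simulated Ldb1-KO comparison, 77% of 100 genes changed by a log2 of 1 and 97% of 100 changed by 2 were recovered, with 16 false calls among 190. In the simulated Isl1-KO comparison the shares were 70% and 96%, with 9 false calls among 175.

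The choices of tests, gene lists and named genes were made before the data were examined. The named genes are Ldb1 and Isl1, a fixed set of islet genes, and per comparison with WT the 6 called genes with the largest rise and the 6 with the largest fall among genes with a mean value of at least 5 in the higher group and all knockout libraries on the same side of the WT mean (4 and 4 in the comparison of the knockouts). Up to 3 called members of each list with the smallest p were added. Some genes that this rule takes are not reported here. Other genes, named beside a count of 5 or fewer, among the genes of opposite direction or among the acinar genes of WT replicate 1, were chosen after their values were seen. The 21 lists cover β-cell identity, islet transcription factors, the secretory machinery, endocrine progenitors, α-cells, δ-, PP- and ε-cells, disallowed genes, acinar, duct, endothelial, immune, mesenchyme and glia or neuron cells, the unfolded protein response, immediate-early and stress genes, oxidative phosphorylation, glycolysis, the cell cycle, LDB and LIM complexes, the response to lactogens and growth hormone, and cholesterol synthesis. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 21 lists, and again with an estimated correlation. With the estimated correlation the calls held for α-cell genes in Ldb1-KO against WT, in 22 of 30 alternatives as well, and for cell cycle genes in Ldb1-KO against Isl1-KO, in 26 of 29. These counts include settings that leave out only libraries of the group not compared. Such settings leave the list's change as it was and enter only through the shared estimates of spread and correlation. The estimated correlation was -0.063 for the α-cell list and 0.12 for the cell cycle list.

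Several lists share members with others, among them 16 of 26 β-cell identity genes, 13 of 19 islet transcription factor genes and 5 of 30 secretory machinery genes. WT libraries expressed, at a mean value of at least 5, 5 of 8 α-cell genes, 8 of 12 genes of δ-, PP- and ε-cells, 9 of 12 duct genes, 3 of 3 glia or neuron genes, 1 of 10 immune genes, 0 of 7 endothelial genes and 0 of 3 mesenchyme genes. They expressed 31 of 31 acinar genes because of replicate 1, and 7 of 31 in the other 4 libraries. The trypsin genes among the acinar genes are near-identical copies, so reads could be shared between them.

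The overlap of both knockout comparisons was set beside n1 × n2 / N per direction, beside the 20 ways of splitting the WT libraries into 2 and 3, and, for the covariance and correlation of fold changes, beside 20 simulations in which all 18 libraries were drawn from a normal distribution around 1 mean per gene. This form of the simulation was chosen after the data were seen, because the planned one drew unchanged groups around the observed WT mean, which left the error of the shared WT libraries out. Peak lists were compared with bedtools 2.31.1 at a minimum overlap of 1 bp, against 1000 circular shifts of a list along each chromosome, with a one-sided p. On simulated lists 699 of 699 planted overlaps were found, and 1 was found where 0 were planted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with numpy 2.4.6. Peak positions are given with starts counted from 1.

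Alternatives covered the pseudocount, the filter, the samples in the fit, a test against a 1.5-fold change, the replicate number as a block, the acinar mean as a covariate, each library left out in turn, split WT controls, and the overlap rule and score limit of peaks. Added after the data were seen were the read step as a covariate, the deeper or shallower libraries alone, the Isl1-KO libraries with replicates 1 to 3 or 4 and 5 left out, and the authors' own calls. The test of peaks near changed genes was left out, because an mm9 gene annotation was not used here.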

Results

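RNA sequencing of sorted mouse pancreatic β-cells and chromatin immunoprecipitation followed by sequencing (ChIP-seq) of whole islets were used to ask what LDB1 and ISL1 maintain in mature β-cells. LDB1 is an adaptor protein that binds LIM-domain transcription factors, and ISL1 is a LIM-homeodomain factor of islet cells that is known to partner with it. Total RNA was profiled in 18 libraries, 5 of them labelled WT, 8 Ldb1-KO and 5 Isl1-KO. All 3 groups carried a YFP reporter and MIP-CreERTm, a Cre recombinase driven by an insulin promoter and switched on by tamoxifen, and the knockout groups also carried the alleles that the labels write as Ldb1L/L or Isl1L/L. Lineage-marked cells of male mice were sorted at postnatal day 56 in the WT and Ldb1-KO groups and at day 49 in the Isl1-KO group. Tamoxifen was given at 150 µg per g from day 28 and again from day 35 in the first pair of groups, and at 100 µg per g from day 28 alone in the Isl1-KO group. The Isl1-KO group therefore differed from WT in genotype, age and dose together. The labels do not say that the libraries of a group came from separate mice, so the p-values below measure only the spread between these libraries.

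Expression values were read as log2 of quantile-normalized values plus 1, and differences between groups are on that scale, which understates the change of weakly expressed genes. Absolute read depth was not given, but the lowest values of each library fell on regular steps. The normalized value per step ranged from 0.71 in the deepest library to 1.45 in the shallowest, a 2.03-fold range, and 13353 to 14129 genes per library lay above 0. Correlations between libraries of a group ranged from 0.932 to 0.978. The first principal component, with 25.4% of the variance, placed all WT libraries between -64.4 and -43.2 and all Ldb1-KO libraries between 15.8 and 47.0. The second, with 16%, parted the Isl1-KO group itself, with replicates 1 to 3 between -56.6 and -47.4 and replicates 4 and 5 at -0.19 and 0.76. The other groups were also spread on it, WT from -7.90 to 41.4 and Ldb1-KO from -20.5 to 41.2.

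WT replicate 1 stood apart in genes of exocrine pancreas. Its mean over 31 acinar genes, which encode digestive enzymes and related proteins, was 9.99, against 1.26 to 1.71 in the other 4 WT libraries, 1.85 to 5.43 in the Ldb1-KO libraries and 1.30 to 4.05 in the Isl1-KO libraries. Its mean over 12 duct genes was also high for the group, at 5.92 against 4.43 to 4.70.

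**Figure D1:**
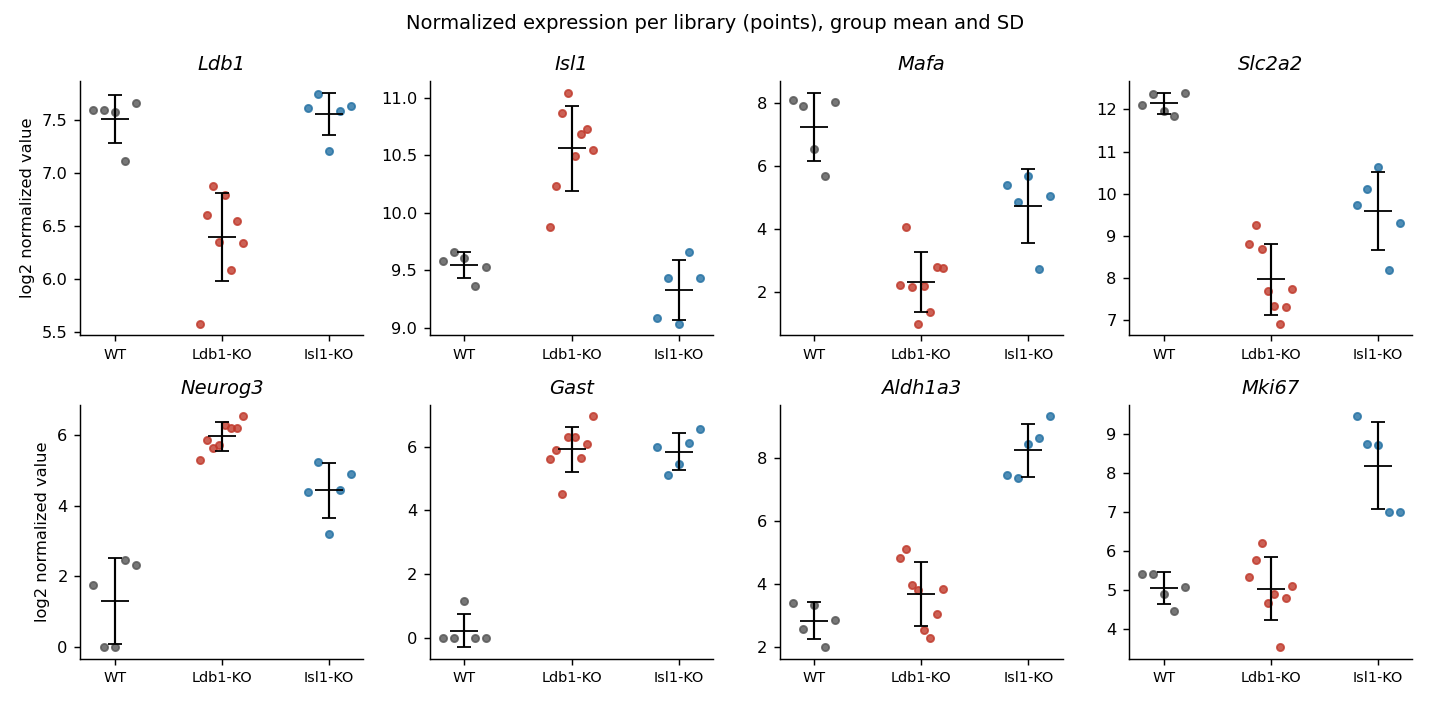
Log2 normalized value (vertical axis) of 8 genes in the 5 WT, 8 Ldb1-KO and 5 Isl1-KO libraries. Each point is a library, and the horizontal bar with whiskers is the group mean with its SD. Mafa and Slc2a2 were lower in both knockout groups than in WT, and Mki67 lay between 7.0 and 9.46 in the 5 Isl1-KO libraries and between 3.53 and 6.21 in the other libraries.

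The first comparison asked which genes differed between the β-cell libraries labelled Ldb1-KO and WT. Ldb1 itself lay at 7.51 ± 0.22 (SD, n = 5) in WT, 6.40 ± 0.42 (SD, n = 8) in Ldb1-KO and 7.55 ± 0.20 (SD, n = 5) in Isl1-KO, so it fell by 1.11 in Ldb1-KO (SE 0.18, adjusted p = 4.35e-05) and was below the WT mean in 8 of 8 libraries. Of 26 genes that define the mature β-cell 16 fell, among them both insulin genes, the insulin gene activator Mafa and the glucose transporter gene Slc2a2, while 1 rose and 9 did not pass (set adjusted p = 0.0530 with an estimated correlation). Of 21 endocrine progenitor genes 6 rose and 3 fell (set adjusted p = 0.240 with an estimated correlation), and those that rose included Neurog3, the factor that starts endocrine differentiation, and Gast, which encodes the hormone gastrin. Of 16 immediate-early and stress genes 10 rose, and of 20 cholesterol synthesis genes 10 fell, with set adjusted p = 0.240 and 0.146 with an estimated correlation.

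In all, 1434 genes were higher and 1491 lower in Ldb1-KO than in WT among 13501 tested, 649 and 555 of them by at least 2-fold. Among the same genes, the authors' deposited table called 1112 higher and 1486 lower, of which 1015 and 1324 were also called here, with 0 in opposite directions.

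The largest rises were those of Sval2 (6.24, SE 0.35), Anxa10 (6.15, SE 0.37), Serpina7 (5.99, SE 0.18), Gast (5.68, SE 0.33), Ros1 (5.31, SE 0.30) and Dnahc11 (5.31, SE 0.36), each with an adjusted p of 1.70e-10 or less. Serpina7, which encodes thyroxine-binding globulin, went from 7.54 ± 0.23 (SD, n = 5) to 13.54 ± 0.20 (SD, n = 8), a 63.7-fold change of the normalized value plus 1. The largest falls were those of Trpm5 (fell by 5.76, SE 0.37), Lrrc55 (fell by 5.70, SE 0.47), Cox6a2 (fell by 5.25, SE 0.74), Mafa (fell by 4.94, SE 0.53), Matn2 (fell by 4.35, SE 0.30) and Itgad (fell by 4.30, SE 0.75). Trpm5 encodes a cation channel of β-cells. These genes were taken only from those with all 8 Ldb1-KO libraries on the same side of the WT mean. With the shallower libraries alone Itgad did not pass (adjusted p = 0.0778).

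Of 26 β-cell identity genes, 16 fell, 1 rose and 9 passed in neither direction, with the same counts when adjusted over the list alone. The list was lower as a set (camera adjusted p = 8.46e-13), but adjusted p = 0.0530 with an estimated correlation, and 16 of its members also belong to other lists. Mafa fell from 7.26 ± 1.08 (SD, n = 5) to 2.32 ± 0.94 (SD, n = 8), with an adjusted p of 6.23e-07. Slc2a2 fell from 12.14 ± 0.24 to 7.97 ± 0.84 (adjusted p = 9.06e-07). Pdx1, a transcription factor of pancreas development and β-cells, fell by 2.02 (SE 0.13, adjusted p = 6.39e-11), Glp1r, the receptor of the incretin GLP-1, fell by 2.94 (SE 0.20, adjusted p = 2.01e-10) and Ucn3 by 3.30 (SE 0.30, adjusted p = 1.27e-07). Nkx6-1 fell by 0.88 (SE 0.16, adjusted p = 2.39e-04). Ins1 fell by 2.83 (SE 0.36) and Ins2 by 2.95 (SE 0.48). Their values are steps of the coarse ladder of top values, and reads of these near-identical genes could have been split between them. The member that rose was Rfx6, another islet transcription factor, at 9.54 ± 0.27 against 8.52 ± 0.22 in WT.

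Among 19 islet transcription factor genes, 3 rose and 5 fell, also when adjusted over the list alone, and the list did not move as a set (adjusted p = 0.414). Isl1 was among those that rose, from 9.55 ± 0.11 (SD, n = 5) to 10.56 ± 0.37 (SD, n = 8), a rise of 1.01 (SE 0.15, adjusted p = 2.78e-05) seen in 8 of 8 libraries. Of 30 genes of the secretory machinery, 6 rose and 9 fell (9 and 10 adjusted over the list alone), and the set test did not pass (adjusted p = 0.481). Chgb, which encodes the granule protein chromogranin B, rose by 3.76 (SE 0.32), to the top ranks of the libraries, and Pam, which encodes an enzyme that amidates peptide hormones, rose by 1.42 (SE 0.12). The Chgb values in Ldb1-KO were all 17.975 or 18.286, steps of the coarse ladder, so its size and SE depend on rank. In the authors' deposited table the Chgb log2 fold change was 3.33.

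Of 21 endocrine progenitor genes, 6 rose and 3 fell (7 and 3 adjusted over the list alone), and the list was higher as a set (adjusted p = 0.0300), but adjusted p = 0.240 with an estimated correlation. Without WT replicate 4 its adjusted p was 0.0567, with another filter or a pseudocount of 10 it was between 0.0537 and 0.0835, and with the deeper libraries alone it was 0.0928. Neurog3 rose from 1.30 ± 1.22 (SD, n = 5) to 5.96 ± 0.41 (SD, n = 8), by 4.65 (SE 0.40, adjusted p = 7.55e-09), and Bambi rose from 7.15 ± 0.51 to 9.15 ± 0.44. The 3 that fell were Dll1, Jag2 and Insm1, which encode 2 Notch ligands and a transcription factor.

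Of 8 α-cell genes, 4 rose and 0 fell (6 rose adjusted over the list alone), and the list was higher as a set (adjusted p = 0.00148), a call that held with an estimated correlation (adjusted p = 0.0400). The latter was lost without WT replicate 3 (adjusted p = 0.0793), without Ldb1-KO replicate 7 or 8 (adjusted p = 0.0509 and 0.0568), with a pseudocount of 10 or no filter (adjusted p = 0.0546 and 0.0651), and with the deeper or shallower libraries alone (adjusted p = 0.115 and 0.161). The estimated correlation of these 8 genes was -0.063, so that test made no allowance for genes that move together. Tmem27 rose by 2.14 (SE 0.17), Ttr by 2.51 (SE 0.39) and Gcg, which encodes glucagon, by 2.51 (SE 0.75, adjusted p = 0.0242), each in 8 of 8 libraries. Tmem27 and Ttr were already high in the WT libraries, at 11.84 to 12.29 and 10.49 to 11.5. Their rises therefore do not by themselves show a gain of α-cell expression. Without WT replicate 2 the Gcg difference was 2.21 with an adjusted p of 0.0703, and with the deeper or shallower libraries alone, which leaves fewer libraries, it was 1.95 and 3.0 with adjusted p = 0.0594 and 0.238. Irx2 rose by 1.64 (SE 0.51, adjusted p = 0.0234), but its adjusted p was 0.0983 without WT replicate 4, 0.0638 without WT replicate 5, and 0.121 and 0.0982 with the deeper or shallower libraries alone. Of 12 genes of δ-, PP- and ε-cells, 2 rose and 1 fell, also when adjusted over the list alone (set adjusted p = 0.223). Etv1 rose by 3.10 (SE 0.25). Sst, which encodes somatostatin, differed by 1.27 (SE 0.42, adjusted p = 0.0390). Its call was lost without WT replicate 2, 3, 4 or 5 or without Ldb1-KO replicate 1, 2, 3, 7 or 8, with an adjusted p of up to 0.106, and with the deeper libraries alone the difference was 0.59 (adjusted p = 0.0883), with the shallower ones 1.81 (adjusted p = 0.118). Ppy differed by 0.90 (SE 0.43, adjusted p = 0.157) and Ghrl by 0.64 (SE 0.50, adjusted p = 0.404), and neither passed, but without Ldb1-KO replicate 4 Ppy did, at 1.11 with an adjusted p of 0.0487, and in the authors' deposited table its FDR was 0.0214. Of 12 duct genes, 5 rose and 0 fell, also when adjusted over the list alone (set adjusted p = 0.00712), but adjusted p = 0.240 with an estimated correlation. Ambp rose by 2.06 (SE 0.22), Cftr by 1.89 (SE 0.37) and Spp1 by 3.13 (SE 0.61). The duct mean was 5.10 to 5.94 in the Ldb1-KO libraries, and WT replicate 1, the library with high acinar genes, lay at 5.92.

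Of 16 immediate-early and stress genes, 10 rose and 0 fell (11 rose adjusted over the list alone), with a set adjusted p of 2.95e-06, but adjusted p = 0.240 with an estimated correlation. Klf6 rose by 2.09 (SE 0.22) and Klf4 by 3.01 (SE 0.39). Hspa1b rose by 2.76 (SE 0.40), with the limit that its reads could be shared with the near-identical Hspa1a. Of 20 cholesterol synthesis genes, 10 fell and 0 rose (13 fell adjusted over the list alone), with a set adjusted p of 6.04e-06, but adjusted p = 0.146 with an estimated correlation. Sc4mol fell by 1.28 (SE 0.10), Cyp51 by 1.00 (SE 0.15) and Insig1 by 0.87 (SE 0.17). Of 24 unfolded protein response genes, 11 fell and 3 rose (11 and 4 adjusted over the list alone), with a set adjusted p of 0.00463, but adjusted p = 0.440 with an estimated correlation. Edem1 fell by 0.87 (SE 0.11), Asns by 1.18 (SE 0.16) and Sel1l by 0.83 (SE 0.12).

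The other lists did not pass as sets. Of 15 glycolysis genes 5 fell (5 adjusted over the list alone, set adjusted p = 0.0728), with set adjusted p = 0.0182, 0.0384 and 0.0297 without WT replicate 4 or Ldb1-KO replicate 6 or 8, and 0.0274 and 0.00489 with the deeper or shallower libraries alone. With an estimated correlation these 5 settings gave adjusted p = 0.574, 0.616, 0.575, 0.501 and 0.360. Of 24 cell cycle genes 2 rose and 8 fell (2 and 10 adjusted over the list alone, set adjusted p = 0.234), with adjusted p = 0.0264 in the deeper libraries alone, but adjusted p = 0.501 there with an estimated correlation. Of 14 genes of the response to lactogens and growth hormone 8 rose and 2 fell (8 and 3 adjusted over the list alone, set adjusted p = 0.252). Tph1, which encodes the enzyme that starts serotonin synthesis, rose by 1.70 (SE 0.36). Of 28 oxidative phosphorylation genes 2 rose and 1 fell (2 and 0 adjusted over the list alone, set adjusted p = 0.481). Of 15 genes of LDB and LIM complexes 3 rose and 2 fell, also when adjusted over the list alone (set adjusted p = 0.513). The 2 that fell were Ldb1 and Lmo1, and this list's mean change was slightly negative at -0.0069 while its median, 0.16, and its test pointed up. Of 8 genes that β-cells normally repress, here called disallowed genes, 2 rose and 1 fell (3 and 1 adjusted over the list alone, set adjusted p = 0.343). Of 31 acinar genes 0 rose and 1 fell (0 adjusted over the list alone, set adjusted p = 0.749), with a mean change of -0.017 and a median of 0.017. Without WT replicate 1 its mean change was 1.67 and its set adjusted p 1.65e-05, but adjusted p = 0.546 with an estimated correlation. Of 7 endothelial genes 1 fell (0 adjusted over the list alone, set adjusted p = 0.218), with adjusted p = 0.0207 in the deeper libraries alone, but adjusted p = 0.403 there with an estimated correlation. Of 10 immune, 3 mesenchyme and 3 glia or neuron genes 0 passed, also over each list alone (set adjusted p = 0.481, 0.234 and 0.953), and the glia or neuron test pointed down while the mean and median changes, 0.087 and 0.19, pointed up.

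**Figure D2:**
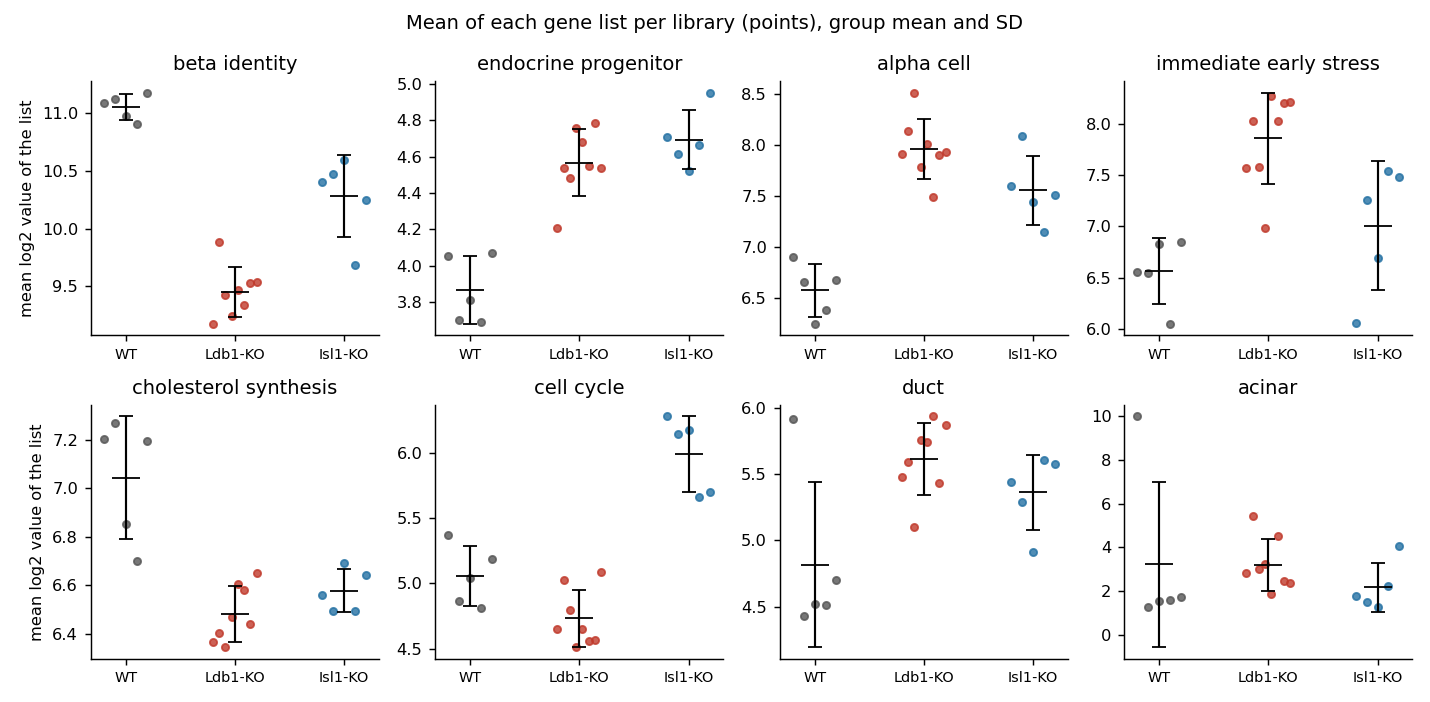
Mean log2 normalized value (vertical axis) of 8 gene lists in each library of the 3 groups. Each point is a library, and the bar with whiskers is the group mean with its SD. The β-cell identity mean was 9.18 to 9.88 in Ldb1-KO, 9.69 to 10.59 in Isl1-KO and 10.91 to 11.18 in WT, and the acinar mean of WT replicate 1 stood apart at 9.99.

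The second comparison asked which genes differed between the libraries labelled Isl1-KO and WT. Isl1 itself lay at 9.33 ± 0.26 (SD, n = 5) in Isl1-KO and 9.55 ± 0.11 (SD, n = 5) in WT, a difference of -0.22 (SE 0.17, adjusted p = 0.431) that did not pass. The table holds 1 value for the whole gene and the deleted part was not resolved, so this value checks neither the deletion nor the labels. Of 26 β-cell identity genes 11 fell and 1 rose, and of 21 endocrine progenitor genes 6 rose, with set adjusted p = 0.246 and 0.241 with an estimated correlation. Of 24 cell cycle genes 10 rose, among them the proliferation marker Mki67, with set adjusted p = 0.127 with an estimated correlation. Aldh1a3, which encodes a retinaldehyde dehydrogenase, rose by 5.42 (SE 0.48). Of 15 glycolysis genes 5 fell and of 20 cholesterol synthesis genes 7 fell, with set adjusted p = 0.448 and 0.241 with an estimated correlation.

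In all, 948 genes were higher and 1133 lower in Isl1-KO than in WT, 516 and 398 of them by at least 2-fold. Among the same genes, the authors' deposited table called 748 higher and 1259 lower, of which 615 and 989 were also called here, with 0 in opposite directions. The counts were 510 and 603 when Isl1-KO replicates 1 to 3, which stood apart on the second principal component, were left out, and 1323 and 1523 when replicates 4 and 5 were left out.

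The largest rises were those of Wdr72 (7.01, SE 0.69), Gast (5.61, SE 0.37), Aldh1a3, Ros1 (5.19, SE 0.33), Cartpt (5.10, SE 0.44) and Serpina7 (5.07, SE 0.20), each with an adjusted p of 2.46e-07 or less. Wdr72 went from 1.11 ± 1.02 (SD, n = 5) to 8.12 ± 1.29 (SD, n = 5) and lay at 1.06 ± 1.31 (SD, n = 8) in Ldb1-KO. Aldh1a3 went from 2.82 ± 0.58 to 8.24 ± 0.83, and Cartpt encodes a neuropeptide. Among the largest falls were those of Meox1 (fell by 4.66, SE 0.37), Tmsb15b2 (fell by 4.10, SE 0.31), Slc28a2 (fell by 3.98, SE 0.41), Matn2 (fell by 3.95, SE 0.33) and Trpm5 (fell by 3.91, SE 0.41). Tmsb15b2 has a near-identical copy, so its value could include reads of that copy. These genes were taken only from those with all 5 Isl1-KO libraries on the same side of the WT mean.

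Of 26 β-cell identity genes, 11 fell and 1, Rfx6, rose (13 and 2 adjusted over the list alone), with a set adjusted p of 2.51e-05, but adjusted p = 0.246 with an estimated correlation. Slc30a8, which encodes the zinc transporter of insulin granules, fell by 1.78 (SE 0.19, adjusted p = 3.71e-07), Pdx1 by 1.22 (SE 0.14, adjusted p = 2.37e-06), Glp1r by 1.54 (SE 0.22), Slc2a2 by 2.55 (SE 0.46) and Mafa by 2.51 (SE 0.59, adjusted p = 0.00601). Ucn3 fell by 1.07 (SE 0.34, adjusted p = 0.0382), a call that was lost without any 1 of the 5 WT libraries or without Isl1-KO replicate 1, 2, 4 or 5, with an adjusted p of up to 0.0849, and the difference was -0.63 (adjusted p = 0.169) with replicates 4 and 5 left out and -1.74 (adjusted p = 0.00440) with replicates 1 to 3 left out. Ins1 differed by -1.10 (SE 0.40, adjusted p = 0.0758), Ins2 by -0.88 (SE 0.53, adjusted p = 0.293) and Nkx6-1 by 0.0013 (SE 0.18, adjusted p = 0.997), and these 3 did not pass. The Ins1 difference passed without Ldb1-KO replicate 2 or 4, which enter only through the shared estimate of the spread, with adjusted p = 0.0164 and 0.0421, and with Isl1-KO and WT alone in the fit, with adjusted p = 6.49e-04. With the shallower libraries alone Ins1 and Ins2 both passed (adjusted p = 4.51e-04 and 0.0138), and the FDR of Ins1 in the authors' deposited table was 7.60e-04. Among 19 islet transcription factor genes, 3 rose and 3 fell, also when adjusted over the list alone (set adjusted p = 0.446), with a rise of 1.18 (SE 0.19) in Rfx3 and 0.93 (SE 0.18) in Rfx6. With Isl1-KO replicates 1 to 3 left out the Rfx6 difference was 0.51 with an adjusted p of 0.143, and the transcription factor list was lower as a set (adjusted p = 0.0350), but adjusted p = 0.305 with an estimated correlation.

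Of 24 cell cycle genes, 10 rose and 0 fell (14 rose adjusted over the list alone), with a set adjusted p of 2.78e-06, but adjusted p = 0.127 with an estimated correlation. Mki67 rose from 5.05 ± 0.40 (SD, n = 5) to 8.19 ± 1.12 (SD, n = 5), by 3.14 (SE 0.47, adjusted p = 1.12e-04). Top2a, a topoisomerase gene of dividing cells, rose by 2.08 (SE 0.30) and Mcm5, a DNA replication gene, by 1.57 (SE 0.31). Both sets of Isl1-KO libraries showed the Mki67 rise, which was 1.96 with replicates 1 to 3 left out and 3.93 with replicates 4 and 5 left out. Without replicates 1 to 3 the Mcm5 difference was 1.32 with an adjusted p of 0.0728.

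Of 21 endocrine progenitor genes, 6 rose and 0 fell (6 rose and 1 fell adjusted over the list alone), with a set adjusted p of 0.0181, but adjusted p = 0.241 with an estimated correlation. Neurog3 rose by 3.13 (SE 0.45, adjusted p = 2.80e-05). Of 8 α-cell genes, 2 rose and 0 fell (4 rose adjusted over the list alone), with a set adjusted p of 0.0202, but adjusted p = 0.127 with an estimated correlation. Tmem27 rose by 1.25 (SE 0.18) and Ttr by 1.64 (SE 0.43), and the Ttr call was lost, with adjusted p = 0.0965 and 0.0536, when either set of Isl1-KO libraries was left out, and with the shallower libraries alone (adjusted p = 0.190). Both genes were already high in WT, as given above. Gcg differed by 2.39 (SE 0.83, adjusted p = 0.0649) and did not pass. Without Isl1-KO replicate 4, whose Gcg value was 7.92 against 10.37 to 12.67 in the others, the difference was 3.18 with an adjusted p of 0.00466, and without Ldb1-KO replicate 3 its adjusted p was 0.0485. With Isl1-KO replicates 1 to 3 left out it was 0.46 (adjusted p = 0.839), and with replicates 4 and 5 left out 3.68 (adjusted p = 0.00164). The FDR of Gcg in the authors' deposited table was 4.34e-07. Of 12 genes of δ-, PP- and ε-cells, 1 rose and 1 fell, also when adjusted over the list alone (set adjusted p = 0.431). With Isl1-KO replicates 4 and 5 left out the list's adjusted p was 0.0293, but adjusted p = 0.334 with an estimated correlation. Etv1 rose by 3.02 (SE 0.27) and Rbp4 fell by 1.63 (SE 0.21). Sst, Ppy and Ghrl differed by 0.96 (SE 0.46), 0.81 (SE 0.48) and -0.49 (SE 0.56), and none of these 3 passed with all libraries. Sst and Ppy depended on the set of Isl1-KO libraries. With replicates 4 and 5 left out they differed by 1.82 (adjusted p = 8.18e-04) and 1.57 (adjusted p = 0.0136), and with replicates 1 to 3 left out both differed by -0.33 (adjusted p = 0.696 and 0.780). Without Isl1-KO replicate 4 alone Sst differed by 1.33 (adjusted p = 0.0371), and its FDR in the authors' deposited table was 0.0443. Of 12 duct genes, 4 rose and 0 fell, also when adjusted over the list alone (set adjusted p = 0.0202), but adjusted p = 0.341 with an estimated correlation. Ambp rose by 1.42 (SE 0.24) and Cftr by 1.79 (SE 0.41). The duct list's adjusted p was 0.0754 when Isl1-KO replicates 4 and 5 were left out.

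Of 20 cholesterol synthesis genes, 7 fell and 0 rose (8 fell adjusted over the list alone), with a set adjusted p of 1.51e-04, but adjusted p = 0.241 with an estimated correlation. Sc4mol fell by 0.59 (SE 0.11) and Cyp51 by 0.75 (SE 0.16), and the adjusted p of Cyp51 was 0.0534 with the shallower libraries alone. Of 15 glycolysis genes, 5 fell and 0 rose, also when adjusted over the list alone (set adjusted p = 0.00348), but adjusted p = 0.448 with an estimated correlation. Aldoc fell by 1.37 (SE 0.22) and Pfkp by 0.70 (SE 0.13). Of 30 secretory machinery genes, 5 rose and 6 fell (10 and 7 adjusted over the list alone, set adjusted p = 0.179), with adjusted p = 0.0220 when Isl1-KO replicates 4 and 5 were left out, but adjusted p = 0.334 with an estimated correlation. Chgb rose by 3.33 (SE 0.35), again with values on the coarse ladder, and Scg5 by 1.60 (SE 0.15).

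The remaining lists did not pass as sets. Of 16 immediate-early and stress genes 4 rose (5 adjusted over the list alone, set adjusted p = 0.0641), with set adjusted p = 0.0359, 0.0267, 0.00175 and 0.0265 without WT replicate 3 or 5 or Isl1-KO replicate 1 or 3, 9.75e-04 with the read step as a covariate, 0.00915 with the shallower libraries alone and 1.31e-04 with Isl1-KO replicates 1 to 3 left out. With an estimated correlation these 7 settings gave adjusted p = 0.626, 0.648, 0.430, 0.642, 0.394, 0.627 and 0.226. Of 14 genes of the response to lactogens and growth hormone 3 rose and 3 fell (5 and 3 adjusted over the list alone, set adjusted p = 0.431). For the next lists the count adjusted over the list alone was the same. Of 24 unfolded protein response genes 2 rose and 1 fell (set adjusted p = 0.979), of 28 oxidative phosphorylation genes 2 fell (set adjusted p = 0.181, and 0.00965 with Isl1-KO replicates 4 and 5 left out, but adjusted p = 0.633 then with an estimated correlation), and of 15 genes of LDB and LIM complexes 1, Lmo1, fell (set adjusted p = 0.948). Of 8 disallowed genes 2 rose and 1 fell (set adjusted p = 0.741), of 10 immune genes 1 rose and 1 fell (set adjusted p = 0.194), of 3 mesenchyme genes 1 fell (set adjusted p = 0.179) and of 3 glia or neuron genes 1 fell (set adjusted p = 0.741). Of 31 acinar and 7 endothelial genes 0 passed (set adjusted p = 0.166 and 0.181). Without WT replicate 2, 3, 4 or 5 or Isl1-KO replicate 5 the acinar set adjusted p was 0.0229, 0.0359, 0.0347, 0.0278 and 0.0428, but adjusted p = 0.742 or more in each with an estimated correlation. Without WT replicate 1 the acinar mean change went from -1.05 to 0.64. The disallowed list's test pointed up while its mean and median changes, -0.19 and -0.17, pointed down, and the LDB and LIM list had a mean of -0.12, a median of 0.062 and a test that pointed down.

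The third comparison set Ldb1-KO against Isl1-KO directly. These groups differed in genotype, age, dose and rounds of tamoxifen together, so their difference is not that between both knockout effects alone. In Ldb1-KO, 17 of 24 cell cycle genes and 15 of 26 β-cell identity genes were lower than in Isl1-KO, and 5 of 16 immediate-early and stress genes were higher. With an estimated correlation the set call held for the cell cycle (adjusted p = 0.0169) but not for the other lists (adjusted p = 0.110 and 0.334). Isl1 was higher by 1.23 (SE 0.15, adjusted p = 1.63e-05) and Ldb1 differed by -1.16 (SE 0.18). In all, 940 genes were higher and 852 lower, 292 and 315 of them by at least 2-fold. The authors' deposited table called 719 higher and 612 lower, of which 649 and 557 were also called here, with 0 in opposite directions.

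The counts depended on which Isl1-KO libraries were used. They were 561 higher and 520 lower without Isl1-KO replicate 3, and 593 higher without replicate 1. With replicates 1 to 3 left out they were 153 and 183, and with replicates 4 and 5 left out they were 1669 and 1335.

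The genes with the largest differences above Isl1-KO were S100z (6.56, SE 0.25), Kcnj3, Meox1 (3.52, SE 0.33) and Gpr64 (3.37, SE 0.33). Those below it were Wdr72 (-7.06, SE 0.62), Aldh1a3 (-4.57, SE 0.44), Inpp4b (-4.04, SE 0.54) and Sfrp5 (-3.83, SE 0.38). Inpp4b differed by -2.48 (adjusted p = 0.0411) with Isl1-KO replicates 1 to 3 left out and by -5.08 (adjusted p = 1.66e-06) with replicates 4 and 5 left out. S100z lay at 6.96 ± 0.33 (SD, n = 8) in Ldb1-KO, 4.13 ± 0.37 (SD, n = 5) in WT and 0.41 ± 0.56 (SD, n = 5) in Isl1-KO. Kcnj3, a potassium channel gene, was listed at 0 in all 5 WT libraries and lay at 4.57 ± 0.40 (SD, n = 8) in Ldb1-KO. In Isl1-KO it lay at 0.90 ± 1.24 (SD, n = 5), a difference of 3.67 (SE 0.40). That difference was 2.31 (adjusted p = 0.00176) with Isl1-KO replicates 1 to 3 left out and 4.57 (adjusted p = 1.78e-08) with replicates 4 and 5 left out.

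Of 24 cell cycle genes, 17 were lower in Ldb1-KO than in Isl1-KO and 0 higher, also when adjusted over the list alone (set adjusted p = 3.28e-12), and this call held with an estimated correlation (adjusted p = 0.0169), but not with Isl1-KO replicates 1 to 3 left out or the shallower libraries alone (adjusted p = 0.0799 and 0.104). Top2a differed by -2.73 (SE 0.27) and Mki67 by -3.15 (SE 0.42). Of 26 β-cell identity genes, 15 were lower and 0 higher (16 and 1 adjusted over the list alone), with a set adjusted p of 3.67e-09, but adjusted p = 0.110 with an estimated correlation. Abcc8, a subunit gene of the ATP-sensitive potassium channel, differed by -1.23 (SE 0.17), Ucn3 by -2.23 (SE 0.30), Glp1r by -1.40 (SE 0.20), Mafa by -2.42 (SE 0.53), Pdx1 by -0.80 (SE 0.13), Nkx6-1 by -0.88 (SE 0.16), Ins1 by -1.74 (SE 0.36) and Ins2 by -2.07 (SE 0.48). Of these 8 genes, Mafa, Pdx1, Nkx6-1, Glp1r, Ins1 and Ins2 did not pass when Isl1-KO replicates 1 to 3 were left out, with Mafa then at -1.56 (adjusted p = 0.319). Slc2a2 differed by -1.62 (SE 0.41, adjusted p = 0.0153) and Neurog3 by 1.53 (SE 0.40, adjusted p = 0.0134). Without Isl1-KO replicate 3 alone these 2 calls were lost, at -1.36 (adjusted p = 0.0524) and 1.22 (adjusted p = 0.0638). With Isl1-KO replicates 1 to 3 left out Slc2a2 and Neurog3 differed by -0.78 (adjusted p = 0.525) and 1.29 (adjusted p = 0.246), and with the shallower libraries alone by -0.93 (adjusted p = 0.191) and 0.80 (adjusted p = 0.370). With a pseudocount of 0.1 Neurog3 differed by 1.58 with an adjusted p of 0.210.

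Of 16 immediate-early and stress genes, 5 were higher in Ldb1-KO than in Isl1-KO and 0 lower (9 higher adjusted over the list alone, set adjusted p = 7.51e-05), but adjusted p = 0.334 with an estimated correlation. With Isl1-KO replicates 1 to 3 left out the list's adjusted p was 0.0618, and with the shallower libraries alone it was 0.488. Klf6 was higher by 1.24 (SE 0.22), and by 0.77 with an adjusted p of 0.0928 with those 3 libraries left out, and its adjusted p was 0.0739 with the shallower libraries alone. Of 24 unfolded protein response genes, 10 were lower and 1 higher (10 and 2 adjusted over the list alone, set adjusted p = 6.65e-05), but adjusted p = 0.291 with an estimated correlation, and Edem1 differed by -0.81 (SE 0.11). Of 30 secretory machinery genes, 11 were lower and 3 higher (14 and 3 adjusted over the list alone, set adjusted p = 6.75e-04), but adjusted p = 0.110 with an estimated correlation. Its adjusted p was 0.159 with Isl1-KO replicates 1 to 3 left out. Of 28 oxidative phosphorylation genes, 5 were higher and 0 lower (6 adjusted over the list alone, set adjusted p = 0.0128), but adjusted p = 0.844 with an estimated correlation. Without Isl1-KO replicate 2 or 3 or Ldb1-KO replicate 8 the list's adjusted p was 0.0587, 0.0925 and 0.108, and with Isl1-KO replicates 1 to 3 left out its mean change turned from 0.21 to -0.081. With the acinar mean or the read step as a covariate its adjusted p was 0.0646 and 0.0935, and with the shallower libraries alone its mean change was -0.064.

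The other lists did not pass as sets. Higher and lower members numbered 5 and 3 of 21 endocrine progenitor genes, 1 and 0 of 8 α-cell genes, 1 and 0 of 15 glycolysis genes and 1 and 1 of 20 cholesterol synthesis genes, and the set adjusted p values were 0.937, 0.187, 0.351 and 0.290. Among 19 islet transcription factor genes 2 were higher and 4 lower (3 and 6 adjusted over the list alone, set adjusted p = 0.527). Among 12 genes of δ-, PP- and ε-cells 2 were higher and 1 lower (set adjusted p = 0.527), and with Isl1-KO replicates 1 to 3 left out the set adjusted p was 1.42e-04, but adjusted p = 0.178 with an estimated correlation. Gcg, Sst, Ppy and Ghrl differed by 0.12 (SE 0.75), 0.31 (SE 0.42), 0.088 (SE 0.43) and 1.13 (SE 0.50), and none of these 4 passed with all libraries. With Isl1-KO replicates 1 to 3 left out Gcg, Sst and Ppy differed by 2.05 (adjusted p = 0.255), 1.60 (adjusted p = 0.0188) and 1.23 (adjusted p = 0.188), and with replicates 4 and 5 left out by -1.17, -0.55 and -0.67 (adjusted p = 0.195, 0.207 and 0.229). Among 12 duct genes 1 was higher (2 adjusted over the list alone, set adjusted p = 0.527), among 15 genes of LDB and LIM complexes 1 was higher and 1 lower (2 and 1 adjusted over the list alone, set adjusted p = 0.527) and among 14 genes of the response to lactogens and growth hormone 1 was higher and 1 lower (2 and 1 adjusted over the list alone, set adjusted p = 0.720). Among 31 acinar genes 1, Bhlha15, was lower (set adjusted p = 0.220), with set adjusted p = 0.00296 and 0.0444 without WT replicate 1 or Isl1-KO replicate 5, and 0.00406 with only both knockout groups in the fit, but adjusted p = 0.820, 0.858 and 0.816 with an estimated correlation. The Bhlha15 call was lost with Isl1-KO replicates 1 to 3 left out (adjusted p = 0.0666). Among the disallowed, endothelial, immune, mesenchyme and glia or neuron genes 0 passed (set adjusted p = 0.378, 0.881, 0.636, 0.867 and 0.720). Where no count over the list alone is given here, it was the same. The test of the mesenchyme list pointed up with its mean change, 0.18, while its median was -0.093.

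**Figure D3:**
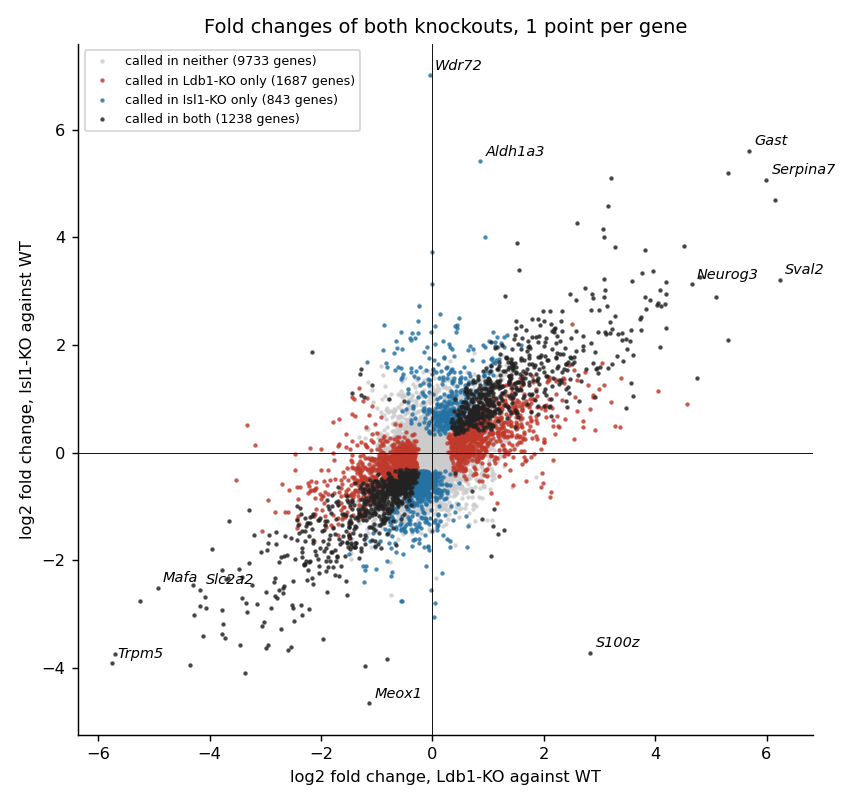
Log2 fold change of each of the 13501 tested genes in Ldb1-KO against WT (horizontal axis) and in Isl1-KO against WT (vertical axis), coloured by the comparison in which the gene passed. Each point is a gene. Of the genes that passed in both, 583 rose in both knockouts, 637 fell in both and 18 went in opposite directions.

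Genes that changed in both knockouts were then counted, because LDB1 and ISL1 are known to act in shared complexes. Serpina7, Gast, Ros1 and Neurog3 rose in both, and Trpm5, Matn2, Mafa, Pdx1, Slc2a2 and Glp1r fell in both. In all, 583 genes were higher and 637 lower in both comparisons, and 18 had opposite directions. Of the 583 genes, 94 were higher and 22 lower in Ldb1-KO than in Isl1-KO when these were compared directly. Of the 637 genes, 76 were lower and 18 higher. Among the 18 genes with opposite directions was S100z, which rose by 2.84 in Ldb1-KO and fell by 3.72 in Isl1-KO. Inpp4b, another of them, fell by 2.17 in Ldb1-KO and rose by 1.87 in Isl1-KO. Its rise lay mostly in Isl1-KO replicates 1 to 3, at 6.49 to 6.91. Replicates 4 and 5 lay at 3.44 and 4.68, against a WT mean of 3.745.

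Both comparisons used the same WT libraries. Independent lists of these sizes would share 101 and 125 genes by chance. With the 5 WT libraries split between the comparisons in 20 ways, the median counts were 229 higher, with a range of 169 to 268, and 258.5 lower, with a range of 151 to 307, where independent lists would share a median of 28.4 and 25.0. Across genes, which are not independent replicates, the fold changes had a correlation of 0.68 and a covariance of 0.33. In 20 simulations without any true change, in which all 18 libraries were drawn, the shared WT libraries alone gave a median correlation of 0.56 and a median covariance of 0.051, and the observed covariance exceeded the simulated one by 0.28. With split WT libraries the medians were 0.50 and 0.27. The simulations called at most 1 gene in a comparison and so give no baseline for the shared counts.

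The ChIP-seq part asked where LDB1 and ISL1 bind in islets of male CD1 mice aged 8 to 10 weeks. The authors' lists held 3359 LDB1 peaks and 2330 ISL1 peaks, all 200 bp wide, in coordinates of the mouse build mm9. Each antibody had 1 list whose peak names carry the word pool, so replicates could not be compared. The score of each peak is the authors' own value with no stated unit, and is used here only to rank peaks within a list. Read depth behind the peaks was not given. A gene annotation of this build was not used here, so peaks are given by position alone.

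Of the LDB1 peaks 1044, or 31.1%, overlapped an ISL1 peak by at least 1 bp, and 1044 ISL1 peaks, or 44.8%, overlapped an LDB1 peak. Over 1000 circular shifts of a list along each chromosome, the mean overlap was 1.30 and the highest 7. The permutation p was thus 0.001, the smallest that 1000 shifts can give. The shifts move peaks to any position in the span, and do not keep to sites where islet chromatin could give peaks with any antibody. The p therefore measures overlap beyond random placement and cannot show that both proteins bind together. Overlap was most frequent among the peaks with the highest scores. When each list was ranked by score and divided into 10 equal parts, 89.0% of LDB1 and 78.1% of ISL1 peaks were shared in the part with the highest scores, against 5.67% and 12.4% in the part with the lowest.

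The LDB1 peak with the highest score, 7.92, lay on chromosome 8 from 107729761 to 107729960 and overlapped an ISL1 peak that started 7 bp away. The next LDB1 peak, with a score of 7.73, lay on chromosome 1 from 53266380 to 53266579 and overlapped the ISL1 peak ranked 2, at 53266389 to 53266588 with a score of 4.89. Of the 8 LDB1 peaks with the highest scores, the exception without an overlap lay on chromosome 2 from 77771780 to 77771979, with a score of 4.99. The ISL1 peak with the highest score, 10.63, lay on chromosome 3 from 53267522 to 53267721 and overlapped no LDB1 peak.

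**Figure D4:**
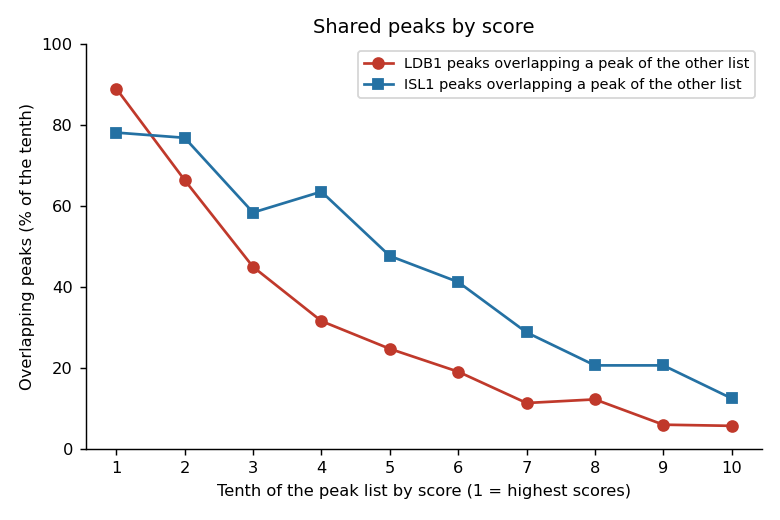
Share of peaks that overlapped a peak of the other list (vertical axis, % of the peaks in a part) in 10 equal parts of each list ranked by score (horizontal axis, 1 is the highest), for LDB1 peaks (circles) and ISL1 peaks (squares). The share went from 89.0% to 5.67% for LDB1 and from 78.1% to 12.4% for ISL1.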

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

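Of the tests below, those of the acinar genes and that of a lower share of β-cells were chosen only after the result was seen. In 405 values checked within groups of 5 or 8 libraries, 41 had a library whose gap to its nearest neighbour took up an unusually large part of the group's range. Chance alone gives about 1 in 20 such groups, or 20.25 here, if values have no ties. In some flagged groups all other libraries had the same value, as for Gpr64 in WT and Meox1 in Isl1-KO. Such ties add to the 41. Ldb1-KO replicate 1 accounts for 7 of the 41 and WT replicate 1 for 6.

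The acinar list mean of WT replicate 1 was 9.99, far above 1.26 to 1.71 in the other WT libraries. Acinar genes picked for their high values in this library were Pnlip at 14.07 against 4.21, Cpb1 at 13.57 against 2.77, Cela2a at 13.49 against 3.54, Cela1 at 13.20 against 3.05 and Prss2 at 12.70 against 2.47 on average in the others. In 96.8% of 31 acinar genes this library lay above the highest other WT library, which is what carry-over of acinar cells or their RNA would give, although the islets were separated from exocrine tissue and the cells sorted, so this source may be a candidate but was found and tested on the same data. Deeper sequencing is argued against by WT replicate 5, which has a similar read step and an acinar mean only 0.25 above that of replicates 2 to 4. A wrong label is argued against by its β-cell identity mean, which lay 0.30 SD of the other WT libraries from their mean. No biological explanation was tested, since the design gives none within a group.

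Cell cycle genes were higher in Isl1-KO than in WT, by 0.94 (SE 0.15) in the list mean. With the read step as a covariate the difference was 0.96 (SE 0.16), which argues against depth as the whole cause. With the mean of Gcg, Sst, Ppy and Pyy as a covariate it was 0.66 (SE 0.11), so these hormone values did not account for all of the difference. They measure carry-over of other endocrine cells only roughly, and a rough covariate can leave a difference even where carry-over is the whole cause. Carry-over therefore stays open for part or all of the difference. Age and tamoxifen dose cannot be told apart from the genotype, because 0 Isl1-KO libraries had the age and dose of the WT libraries. The loss of Isl1 itself therefore stays open, as a hypothesis beside age, dose and carry-over.

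Gcg was higher in Ldb1-KO than in WT by 2.51 (SE 0.76 in a model of this gene alone). With the read step as a covariate the difference was 2.47 (SE 0.78), which argues against depth. With the mean of Sst, Ppy and Pyy as a covariate it was 1.23 (SE 0.54, 95% interval 0.079 to 2.38), an interval just above 0. These 3 hormone genes do not measure α-cells, which express Gcg, so the test cannot decide on carry-over of α-cells. Carry-over of other endocrine cells stays open for part or all of the difference. A lower share of β-cells in the sort cannot be told apart from a change in the cells. For the next list means the SE is over genes and does not measure the spread between libraries. Between libraries the mesenchyme mean had an SD of 0.80 in WT (n = 5) and 0.81 in Ldb1-KO (n = 8). The endothelial list mean changed by -0.77 (SE over genes 0.15), the mesenchyme mean by -1.10 (SE over genes 0.051) and the immune mean by -0.37 (SE over genes 0.21). A fall of any of these had been set as evidence against this explanation, but that bound was wrong, because 0 of 7, 0 of 3 and 2 of 10 members reached a mean value of 5 over all 18 libraries, and genes near the floor exclude nothing, a judgement made after these values were seen.

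Chance in the assignment of libraries to groups was argued against, but not excluded, in all 3 comparisons. In each, 1 of 100 splits, the real one, gave as many called genes, the smallest share that 100 splits can give. Possible splits numbered 1287 for Ldb1-KO against WT, 126 for Isl1-KO against WT and 1287 for Ldb1-KO against Isl1-KO. Splits that mix the real groups also widen the spread within groups, which lowers their counts. The real counts were 2925 for Ldb1-KO against WT, 2081 for Isl1-KO against WT and 1792 for Ldb1-KO against Isl1-KO, and the highest other counts were 32, 162 and 1. The split that gave 162 put Isl1-KO replicates 1 to 3 with WT replicates 2 and 5. The labels do not say that the libraries of a group came from separate mice, so these splits cover the spread between libraries and say nothing of that between mice.

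In WT, replicate 1 stood above the others in Ins1 (17.01), Ins2 (18.29), Gpr64 (0.78) and the duct list mean (5.92), and below them in Chgb (13.96). Replicate 2 stood below in Gcg (7.47) and in Anxa10, listed at 0. Replicate 3 stood above in Gast (1.16). Replicate 4 stood below in Ldb1 (7.11) and Trpm5 (8.72) and above in Tmem27 (12.29).

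In Ldb1-KO, replicate 1 stood above the others in Dnahc11 (8.04), Wdr72 (3.91), Ttr (15.66), Itih5 (6.21), Mgst1 (4.25) and the mean of the disallowed genes (4.78), and below them in Insm1 (6.86). Replicate 2 stood above in Glp1r (7.98) and Lmo1 (0.89) and below in Lrrc55, listed at 0. Replicate 3 stood above in Cenpe (4.22) and the list mean of δ-, PP- and ε-cell genes (6.43), replicate 5 above in Col3a1 (3.63), and replicate 8 below in Casr (6.66).

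In Isl1-KO, replicate 1 stood below the others in Ttr (11.98) and Sdha (9.70) and above them in the normalized value per read step (1.45), as the shallowest library. Replicate 2 stood below in Wdr72 (5.87) and Cyc1 (5.65). Replicate 3 stood above in Ins1 (15.42), Meox1 (1) and Slc28a2 (2.23) and below in Chgb (15.66). Replicate 4 stood below in Mafa (2.73) and Trpm5 (3.14) and above in Pkm2 (10.55) and the mean of the disallowed genes (3.70). Replicate 5 stood above in Col3a1 (1) and Lmo1 (1).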

How the results depend on the processing

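The read step, the depth classes, the Isl1-KO libraries left out in sets and the authors' own calls were alternatives chosen only after the data were seen, and the others were planned. Of 182 results of named genes, 85 kept their side of the threshold under all alternatives run, and of 63 results of lists 42 did, each also in its direction wherever it passed. Over all settings, 314 of 5698 gene values no longer passed, 17 newly passed and 0 that passed on either side turned direction, and of 1842 list values 17 no longer passed, 36 newly passed and 5 turned direction. The counts of called genes moved by less than 1.5 times with other pseudocounts (0.1 and 10), with no filter or a mean of at least 5, with only the compared groups in the fit, with the acinar mean or the read step as a covariate, in the authors' own calls, and, for Ldb1-KO against WT, with the deeper libraries alone. The deeper libraries gave no value for Isl1-KO, of which 1 library was deeper.

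Against a 1.5-fold change, which asks more of each gene, the counts were 346 higher and 307 lower in Ldb1-KO against WT, 173 and 142 in Isl1-KO against WT, 52 and 66 in Ldb1-KO against Isl1-KO, and 122 and 108 in both knockouts. With the shallower libraries alone, which leaves fewer samples, they were 773 and 835, 528 and 526, 373 and 619 between the knockouts, of which 37.6% were higher against 52.5% with all libraries, and 329 and 306 in both. With Isl1-KO replicates 1 to 3 left out they were 510 and 603 in Isl1-KO against WT and 153 and 183 between the knockouts, again with fewer samples. With Isl1-KO replicates 4 and 5 left out they were 1323 and 1523 in Isl1-KO against WT and 1669 and 1335 between the knockouts, a rise despite fewer samples whose cause was not tested. With split WT libraries, which leaves fewer WT samples per comparison, the medians in both knockouts were 229 and 258.5. Among the 1679 LDB1 and 1165 ISL1 peaks with the highest scores, 664 of each list were shared. With at least 50% of the shorter peak the shared number was 966 in each list, and with centres within 500 bp it was 1067 LDB1 and 1061 ISL1 peaks.

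With each library left out in turn, the counts ranged from 1150 to 1529 higher and 1181 to 1552 lower in Ldb1-KO against WT, from 676 to 1058 and 823 to 1200 in Isl1-KO against WT, from 561 to 1207 and 520 to 1031 between the knockouts, and from 449 to 633 and 504 to 661 in both. The acinar mean change in Ldb1-KO against WT ranged from -0.51 to 1.67, the latter without WT replicate 1. With the deeper libraries alone, whose WT libraries are replicates 1 and 5, this change was -2.53. With the shallower libraries alone, which leave out WT replicates 1 and 5, the acinar change was 1.55 in Ldb1-KO and 0.92 in Isl1-KO against WT. The oxidative phosphorylation change between the knockouts was -0.064 with the shallower libraries alone and -0.081 with Isl1-KO replicates 1 to 3 left out, and the cause was not tested.

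With the replicate number as a block the counts were 1632 higher and 1639 lower in Ldb1-KO against WT, 1052 and 1102 in Isl1-KO against WT, 720 and 768 between the knockouts, and 673 and 645 in both. Of the 182 gene results 11 no longer passed with the block, Gcg in Ldb1-KO against WT among them at 2.70 (adjusted p = 0.0659), and of the 63 list results at the preset correlation 2 no longer passed and 2 newly did. With the block and an estimated correlation the α-cell list in Ldb1-KO against WT had adjusted p = 0.128 and the cell cycle list between the knockouts adjusted p = 0.0556. The numbers did not pair the libraries. The 15 pairs with the same number had correlations of their deviations from -0.17 to 0.26, 4 of them over 0.1, and 4 of 15 libraries correlated best with their own number.

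Not run were the alternatives that need counts (other normalizations, count tools and count filters), those for symbols with several rows, of which there were 0, and all that need positions of genes. Endothelial and mesenchyme lists had 0 members with a mean of at least 5 and so gave no value there. Absolute depth is unknown, so no limit of detection is given, and a value of 0 says only that a gene was listed at 0.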

Other observations

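Besides the fixed lists, 201 families of genes that share the start of their symbol were scanned in each comparison, a step chosen after the data were seen. Of 11 clustered protocadherin genes of the Pcdha family, which encode adhesion proteins known from neurons, 9 fell in Isl1-KO against WT (camera adjusted p = 0.00196), but adjusted p = 0.992 with an estimated correlation. These genes share most of their exons, so reads could be split between them. Of 9 Mcm genes 4 rose in Isl1-KO (adjusted p = 0.00557), and of 31 kinesin genes of the Kif family 6 rose (adjusted p = 0.0397), both with adjusted p = 0.992 with an estimated correlation. Between Ldb1-KO and Isl1-KO, 11 of 31 Kif genes and 12 of 59 histone genes were lower in Ldb1-KO (adjusted p = 7.36e-04 and 0.00148), but adjusted p = 0.888 with an estimated correlation in both. Of 40 genes of large ribosomal subunit proteins 11 rose in Ldb1-KO against WT (adjusted p = 0.0483), but adjusted p = 0.992 with an estimated correlation. No family passed with the estimated correlation.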
